A study of Mus musculus with 19 samples.

How the data were processed

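Total RNA from the frontal cortex of 19 mice was labelled with biotin and hybridised to Illumina MouseRef-8 v2.0 bead arrays, 1 array per mouse, per the labels. The deposited table of average bead signals holds intensity values for 25697 probes, exported by GenomeStudio 1.6.0 with no normalization and no error model, per the file headers. Those intensity values include negative numbers, so background had been subtracted before they were deposited. The authors also deposited processed values on a log2 scale, which no header or label describes. Set against the bead signals, their differences between arrays equalled those of log2 signals floored at 1 for 100% of values within a tolerance of 0.001. They are centred per probe by a constant whose definition stays unknown, were not scaled between arrays, and run in the same direction as the signals. Their medians by array lay between -0.6635, in female infected replicate 3, and 0.1969, in female infected replicate 4.

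The correction planned before the data were examined (limma's neqc) needs detection p-values, which the deposited tables used here do not carry. The fallback written at the same time was used: normexp background correction by maximum likelihood with an offset of 16, then log2 and quantile normalization, in limma 3.58.1 under R 4.3.3. Log2 fold changes on this scale understate the change of dim probes. A stand-in detection p was taken from values below 0 and their mirror image about 0, which made up 21.5% to 25.17% of probes per array on the negative side. Probes with a stand-in p below 0.05 on at least 4 arrays were kept (16121), and 1 probe per gene, the one with the highest mean over all arrays, gave 11862 features. Names come from the target column of the table. Against the gene table of GRCm38 patch 6, used for names only, 20443 probes matched a current symbol and 3858 a single synonym, 232 kept the file's name because of a clash, 108 were ambiguous, 1025 had no match and 31 held a name turned into a calendar date. Each printed gene value comes from the 1 chosen probe, and other probes of a gene can disagree: for infection in males, Cd200 stood at -0.49 by the chosen probe and 0.01 by the other, and Rbfox2 at -0.65 and -0.07. The results give the other probes of a gene where one lay under 0.5 of the printed value.

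The 4 groups were fitted as group means over all 19 arrays with lmFit, contrasts.fit and eBayes and without covariates. The contrasts were infection in each sex, its average, the interaction, and sex in control and in infected mice. A gene passed at a Benjamini-Hochberg adjusted p below 0.05, two-sided. Of 37 gene lists fixed before the data were examined, 36 had at least 3 members and were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. The list of pituitary hormone transcripts had too few. Fry asks whether a list moves 1 way without comparing it with other genes, and called 0 lists in females, 1 in males and 1 in the average, B and plasma cell markers in both (adjusted p = 0.0219 and adjusted p = 0.00418). List scores per mouse were compared by exact permutation, for which the smallest two-sided p is 0.00794 in either sex.

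The genes named in the text followed a rule fixed before the data were examined. It took the 12 largest rises and falls past the threshold for each infection contrast and for sex in controls, the 6 named genes with the smallest p where fewer than 6 passed, 4 members of each list past its threshold, and 13 genes named in advance, 1 of which is not reported here. On simulated data with the means and SDs of the 11862 real features and 200 changed genes, the averaged infection contrast recovered 26.9% of 1.2-fold, 86.6% of 1.5-fold and 97% of 2-fold changes. The values were 5.97%, 58.2% and 90.9% for infection in females, and 2.99%, 56.7% and 89.4% for infection in males. For the interaction they were 0%, 16.4% and 81.8%, and a simulated shift of 1 list by 0.2 was not found there (limma camera, adjusted p = 0.747). The simulated noise was normal and independent between genes. It left out the variation that real genes share between arrays and any array that stands apart, so these shares may not hold for the real data.

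The titles number the replicates alike in each group. Deviations from the group means of same-numbered control and infected females correlated at 0.11 to 0.527 over 5 pairs. Every female pair thus met the criterion of 0.1 for treating the numbers as pairs. No label names a pairing, a shared litter or a shared day. The column headers give each mouse its own number, running on from group to group, so a replicate number is only a rank within its group. In males the lowest of the pairs was 0.0867, close to that criterion. Over all 27 same-numbered pairs of groups the range was -0.473 to 0.527, so a pairing of the mice is not established. The highest correlation between any 2 arrays on the signal scale was 0.9964, and no arrays were identical. The slide of each array is not given in the sources used here, so slides could not be tested as batches.

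Alternatives covered the background correction, the scaling between arrays, the authors' processed values, the filter, the probes per gene, the variance model, the replicate block and leaving out each mouse. Added after the data had been seen were a fit without the 4 arrays of lowest array weight (female control replicate 3, male infected replicate 1, male control replicate 1 and female infected replicate 3), fits with the respiratory chain or the striatal list score as a covariate, and a replicate block within each sex.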

Results

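Transcript levels were measured in the frontal cortex of 19 BALB/c mice about 6 months after infection with the Pru strain of Toxoplasma gondii, a protozoan parasite that persists in the brain as tissue cysts. Infected mice had received 400 tachyzoites (2 parasites per microlitre) into the peritoneal cavity, and control mice had received buffer only. The groups were 4 control males, 5 infected males, 5 control females and 5 infected females, with 1 Illumina bead array per mouse. The upper quartile of the bead signal lay between 60.7 and 155.8 units, lowest in female infected replicate 3 and highest in female infected replicate 4, and between 54.44% and 58.34% of the 25697 probes were above background. The number of mice per group limits the precision. After the filter on dim probes, 11862 features were tested, of which 11164 carried a current gene name.

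The comparison of the sexes, which also checks the labels, was led by Y-linked genes. In control mice, Eif2s3y, a Y-linked translation initiation factor subunit gene, had a mean log2 intensity of 7.62 ± 0.15 (SD, n = 4) in males. It was above background in 0 of the 5 control females, at 4.27 ± 0.06 (SD, n = 5), so males were at least 6.32-fold higher (limma, adjusted p = 1.2e-13). The Y-linked RNA helicase gene Ddx3y was lower in females, with a log2 difference, females minus males, of -2.68 (SE 0.27, limma, adjusted p = 2.4e-05). Its probe read above background on all 19 arrays, so the signal in females, which carry no Y chromosome, is not a level of this gene. The Y-linked histone demethylase gene Kdm5d was at least 1.61-fold higher in males (limma, adjusted p = 0.00042). These bounds set the mean of the males against the higher of the dim probe's own signal and the lowest signal above background on each female array. These 3 genes were the only ones past the adjusted threshold, with 0 higher in females, against 697 features at an unadjusted p under 0.05 where 593.1 would pass by chance. Xist, the transcript that silences 1 X chromosome in female cells, was higher in control females than in control males by 0.89 (SE 0.17), with means of 5.87 ± 0.35 (SD, n = 5) and 4.98 ± 0.16 (SD, n = 4), and did not pass (limma, adjusted p = 0.098). A dimmer Xist probe, with a female minus male value of 1.02, passed when every probe was tested. Also not past the threshold were Cd6, a T cell surface receptor gene, at 1.11 (SE 0.21, limma, adjusted p = 0.098; other probes 0.96, 0.91 and -0.08), and Ninl at 0.53 (SE 0.10, limma, adjusted p = 0.095).

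In infected mice, 5 genes differed between the sexes (limma, adjusted p below the threshold), 4 lower and 1 higher in females, with 734 features at an unadjusted p under 0.05. The lower ones were Ddx3y at -2.81 (SE 0.26), the Y-linked demethylase gene Uty at -0.49 (SE 0.08), Eif2s3y at -2.81 (SE 0.11), which was above background in 1 of 5 infected females, and Kdm5d, which was above background in 0 of 5 and at least 1.49-fold higher in males. Ddx3y and Uty read above background on all 19 arrays, females included. A reading above background thus need not mean that the named gene is expressed. The higher one, Kdm6a, the X-linked counterpart of Uty, stood at 9.03 ± 0.16 in infected females (SD, n = 5) and at 8.35 ± 0.28 in infected males (SD, n = 5). Kdm6a was named after its values were seen. The count fell to 3 without male infected replicate 3, female infected replicate 1 or female infected replicate 4, and Kdm6a and Uty then no longer passed. All 9 male arrays lay above all 10 female arrays for Eif2s3y, with the group values drawn in the plot of the sex-linked genes.

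**Figure D1:**
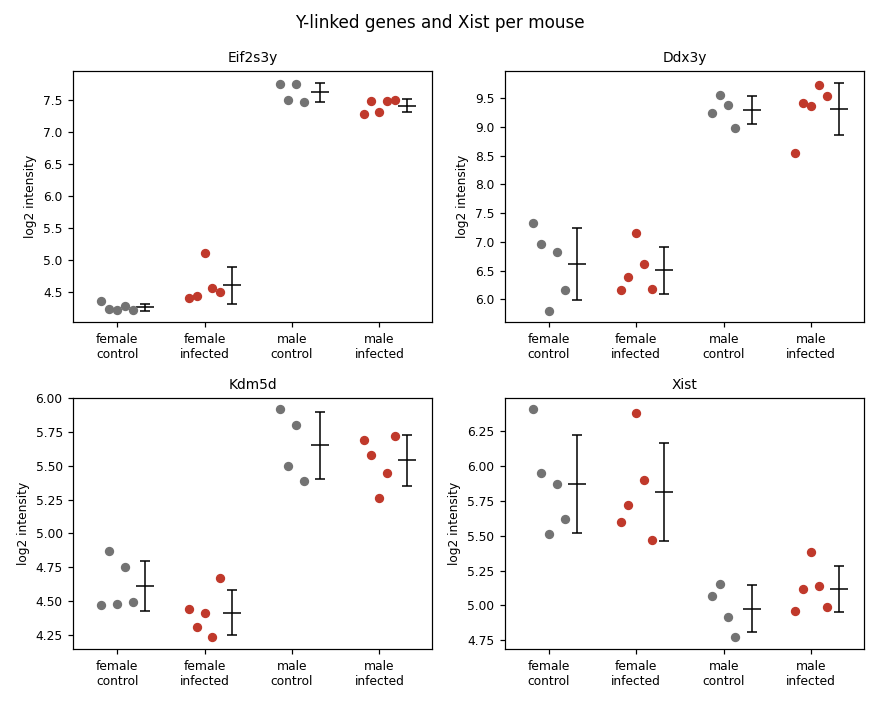
Log2 intensity of Eif2s3y, Ddx3y, Kdm5d and Xist in each mouse (points) of the 4 groups, grey for control and red for infected, with the group mean and SD as a bar beside them. Eif2s3y averaged 7.62 in control males and 4.27 in control females, and Xist averaged 4.98 and 5.87.

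Infection averaged over both sexes was set against the controls to ask what chronic infection changed in the cortex. Genes of the interferon response rose in infected mice as groups, while no single gene passed. Genes of antigen presentation rose with the preset correlation only, with adjusted p = 0.146 for class I and adjusted p = 0.319 for class II with an estimated correlation. In the list of interferon-gamma-induced genes and immunity-related GTPases, which includes effectors that attack the vacuole holding the parasite, 12 of 12 measured members had a positive log2 fold change, with a mean of 0.23. The members with the smallest p were the guanylate-binding protein genes Gbp2 at 0.38 (SE 0.12) and Gbp3 at 0.28 (SE 0.11), the GTPase gene Irgm2 at 0.36 (SE 0.17), and the GTPase gene Ifi47, which was above background in 0 of 4 control males and so has no exact value. The list rose (limma camera, adjusted p = 7.37e-09), and kept its call at adjusted p = 0.0333 with an estimated correlation. Adjusted over the list alone 2 members passed, against 0 over all genes tested. Of the type I interferon-stimulated genes, 13 of 14 were positive, with a mean of 0.17. Among them were Oasl2 at 0.47 (SE 0.14), Parp14 at 0.32 (SE 0.10), Usp18 at 0.24 (SE 0.06) and Ifit3 at 0.22 (SE 0.08). This list rose as well (limma camera, adjusted p = 1.44e-07, and adjusted p = 0.0333 with an estimated correlation), with 3 members passing when adjusted over the list alone and 0 over all genes. With the replicate number as a block both lists kept the preset call, and stood at adjusted p = 0.0704 each with an estimated correlation. Without male infected replicate 1 the estimated correlation gave adjusted p = 0.159 for each.

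Of the genes for antigen presentation on MHC class I, 10 of 11 were positive, with a mean of 0.21 and a median of 0.11. The list rose with the preset correlation (limma camera, adjusted p = 3.6e-06), and the call was lost at adjusted p = 0.146 with an estimated correlation. Its leading member was B2m, the light chain of all MHC class I molecules, at 0.64 (SE 0.16). H2-K1 followed at 0.45 (SE 0.15), H2-T23 at 0.44 (SE 0.17) and H2-M3 at 0.25 (SE 0.11). Adjusted over the list alone 2 members passed, against 0 over all genes. All 5 MHC class II genes were positive, Cd74, the class II invariant chain, at 0.51 (SE 0.33) and H2-Ab1 at 0.38 (SE 0.23), with a list mean of 0.30 (limma camera, adjusted p = 0.00155, and adjusted p = 0.319 with an estimated correlation). That mean fell to 0.12 without male infected replicate 4. The B and plasma cell list had 3 measured members and rose (limma camera, adjusted p = 0.00162, and adjusted p = 0.0333 with an estimated correlation). It was carried by Mzb1, a gene of antibody-secreting cells, which was above background in 0 of 9 control mice, 4 of 5 infected females and 5 of 5 infected males, so that its list mean of 0.36 rests on controls without a measured level. These counts turn on small differences near the floor: male infected replicate 2 counted at 4.95 and female control replicate 2 did not at 4.94. Clearly higher values, from 5.96 to 7.03, lay in female infected replicates 1, 3 and 5 and male infected replicates 4 and 5. Mzb1 passed the filter on dim probes through infected mice alone. In males Mzb1 was at least 1.65-fold higher with infection, and Blnk stood at 0.08 (SE 0.09) in the average. Mzb1 passed when adjusted over the list alone and not over all genes. With an estimated correlation this list stood at adjusted p = 0.0787 under the replicate block and at adjusted p = 0.159 without male infected replicate 1. Without the filter on dim probes the list had 12 members and a mean of 0.13, and the interferon-gamma and type I interferon lists had 20 and 25 with means of 0.14 and 0.11. All 3 calls with an estimated correlation held there, at adjusted p = 0.0421, adjusted p = 0.0421 and adjusted p = 0.0184, and ended without the 4 arrays of lowest weight, at adjusted p = 0.219, adjusted p = 0.236 and adjusted p = 0.219.

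No gene passed in the average over the sexes (limma, 0 of 11862), where 345 features had an unadjusted p under 0.05 and 593.1 would by chance. The smallest p values belonged to H2-Q8, an MHC class I gene, at 0.60 (SE 0.14), Sh2d3c, which was lower and above background in 0 of 5 infected females, the clock-controlled transcription factor gene Dbp at -0.43 (SE 0.11), B2m, Lsm14b at -0.42 (SE 0.10, other probes -0.10 and -0.09) and Slpi, a secreted inhibitor of leukocyte proteases, at 1.17 (SE 0.29). Each had a limma adjusted p of 0.84. With a replicate block within each sex, added after the data had been seen, 1 gene passed in the average, Gm8909, named after its values were seen. Slpi averaged 6.53 ± 0.92 in infected females (SD, n = 5) against 5.36 ± 0.14 in control females (SD, n = 5), and 6.50 ± 1.07 in infected males (SD, n = 5) against 5.33 ± 0.14 in control males (SD, n = 4). The rise was uneven, from 5.37 to 7.27 in infected females and from 5.63 to 8.12 in infected males, with the highest control at 5.54. Female infected replicates 1, 3 and 5 and male infected replicates 4 and 5 lay highest in their groups, for Mzb1 as well. Of the genes named in advance, Igtp stood at 0.37 (SE 0.18), the astrocyte filament gene Gfap at -0.16 (SE 0.16), the cortical layer regulator Fezf2 at 0.18 (SE 0.19) and the dopamine receptor genes Drd1 and Drd2 at -0.09 (SE 0.18) and 0.01 (SE 0.18). Eomes was not above background on any array.

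**Figure D2:**
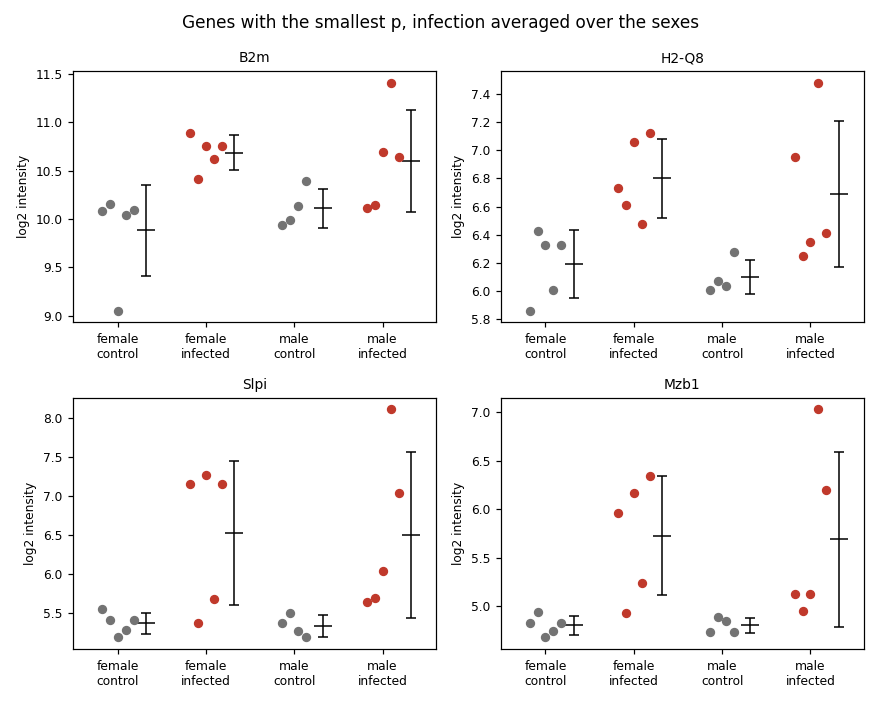
Log2 intensity of B2m, H2-Q8, Slpi and Mzb1 in each mouse (points) of the 4 groups, grey for control and red for infected, with the group mean and SD as a bar. Slpi averaged 5.36 in control and 6.53 in infected females.

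Further lists shifted in the average over the sexes with the preset correlation, and each of these lost its call with an estimated one. Glucocorticoid-induced genes fell (mean -0.18, 4 of 13 positive, limma camera, adjusted p = 0.000325, and adjusted p = 0.109 with an estimated correlation), led by Tsc22d3, which encodes the leucine zipper GILZ, at -0.48 (SE 0.12). Mural and meningeal markers fell (mean -0.14, 3 of 16 positive, adjusted p = 0.00071, and adjusted p = 0.226 with an estimated correlation), with Igfbp2 at -0.28 (SE 0.09) and Igf2 at -0.41 (SE 0.16). Synaptic vesicle and transmission genes fell (mean -0.10, 6 of 21 positive, adjusted p = 0.00806, and adjusted p = 0.152 with an estimated correlation), with Stx1a at -0.24 (SE 0.10). Markers of microglia in the unstimulated brain fell (mean -0.07, 1 of 11 positive, adjusted p = 0.0219, and adjusted p = 0.47 with an estimated correlation), with Fcrls at -0.23 (SE 0.07). Endothelial markers rose (mean 0.09, 11 of 15 positive, adjusted p = 0.0281, and adjusted p = 0.387 with an estimated correlation), led by Ly6a, an interferon-responsive surface antigen gene, at 0.70 (SE 0.20). Monocyte and neutrophil markers rose (mean 0.12, 5 of 7 positive, adjusted p = 0.0219, and adjusted p = 0.31 with an estimated correlation). Hippocampal markers rose (mean 0.24, 7 of 9 positive, adjusted p = 0.0164, and adjusted p = 0.31 with an estimated correlation), and choroid plexus and ependymal markers fell (mean -0.26, 2 of 12 positive, adjusted p = 0.019, and adjusted p = 0.627 with an estimated correlation). Red blood cell transcripts rose (mean 0.13, 6 of 6 positive, adjusted p = 0.0427, and adjusted p = 0.405 with an estimated correlation). Leaving out 1 mouse in turn, the preset call held in 9 of 19 fits for red blood cell and endothelial, 12 for choroid plexus, 15 for hippocampal, monocyte and neutrophil and unstimulated microglia, and 18 for synaptic genes. The largest adjusted p values came without male control replicate 4 for choroid plexus (0.648, mean -0.09), without male control replicate 1 for unstimulated microglia (0.462) and synaptic genes (0.156), without female control replicate 3 for red blood cell (0.453) and monocyte and neutrophil genes (0.0881), without male infected replicate 1 for endothelial (0.211) and without female infected replicate 3 for hippocampal genes (0.0762).

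Cytosolic ribosomal protein genes and nuclear-encoded respiratory chain genes, which move with RNA quality between preparations, had averaged means of 0.17 each, with 48 of 53 and 68 of 74 members positive. Both lists passed with the preset correlation (limma camera, adjusted p = 3.13e-08 and adjusted p = 7.37e-09). Neither passed with an estimated one, at adjusted p = 0.47 each. Without female control replicate 3 both means were 0.05.

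**Figure D3:**
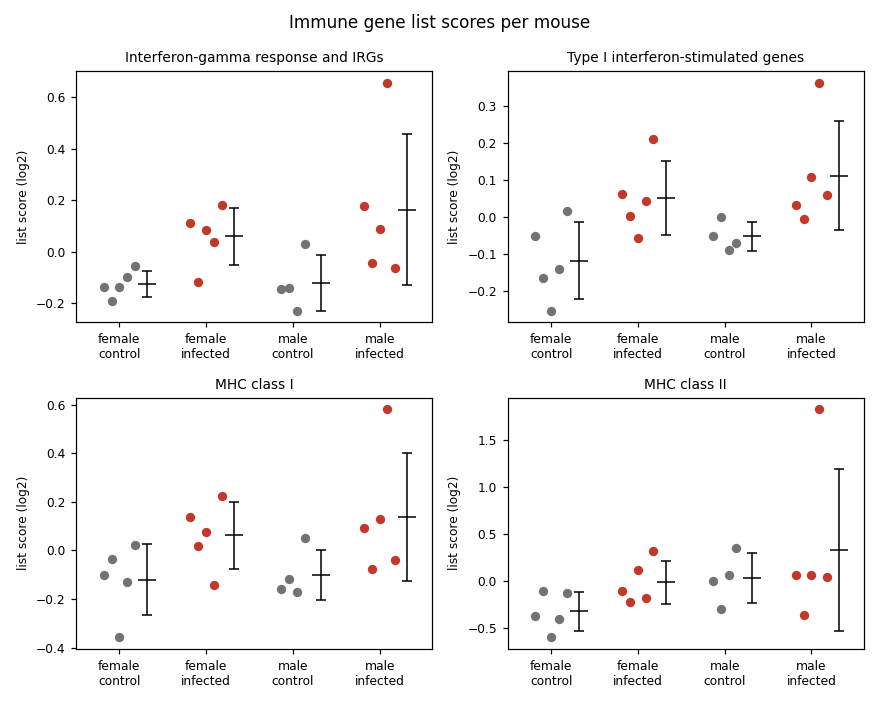
Score of 4 immune gene lists in each mouse (points), the mean over list members of log2 intensity minus the gene's mean over all 19 arrays, grey for control and red for infected, with the group mean and SD as a bar. Male infected replicate 4 had an MHC class II score of 1.83, while the other infected males lay between -0.37 and 0.06.

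The scores of single mice gave the spread behind the list tests. The interferon-gamma list score was -0.13 ± 0.05 in control females and 0.06 ± 0.11 in infected females (SD, n = 5 each, exact permutation test, two-sided, p = 0.0238). In males it was -0.12 ± 0.11 in controls (SD, n = 4) and 0.16 ± 0.29 in infected mice (SD, n = 5, exact permutation p = 0.0714). The type I interferon score had an exact permutation p of 0.0397 in each sex, and the B and plasma cell score 0.00794 in females and 0.0238 in males, with 5 of 5 infected mice above the highest control in either sex. Other lists also had an exact permutation p under 0.05. In females these were hippocampal markers (0.0159). In males they were monocyte and neutrophil markers (0.0317), red blood cell transcripts (0.0397) and endothelial markers (0.0476). Within a sex none of the 36 lists passed after Benjamini-Hochberg adjustment, but a single list at the smallest possible p of 0.00794 adjusts to 0.286, so this count says little. The smallest adjusted p was 0.286 in females and 0.343 in males. With both sexes together and infection permuted within each sex, 3 lists passed: B and plasma cell markers (adjusted exact permutation p = 0.00794), type I interferon-stimulated genes (adjusted exact permutation p = 0.0227) and the interferon-gamma list (adjusted exact permutation p = 0.0299). This joint permutation was added after the data had been seen, and it ignored the replicate numbers. It gave 0 lists without the 4 arrays of lowest weight and 1 list with the authors' processed values.

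In females alone, the genes with the smallest p were Ninl at -0.45 (SE 0.09), Eva1a at -0.46 (SE 0.10), the splicing factor gene Srsf5 at -0.58 (SE 0.13), the semaphorin receptor gene Nrp1 at 0.59 (SE 0.14), the synaptic scaffold gene Mpp3 at -0.46 (SE 0.11) and Armc8 at -0.36 (SE 0.09, other probes -0.26, -0.20 and 0.02). None passed (limma, 0 of 11862 genes, smallest adjusted p = 0.626), with 480 features at an unadjusted p under 0.05. With the 5 numbered female pairs as a block 0 genes passed as well (limma), with 955 features at an unadjusted p under 0.05 against 593.1 by chance. By camera with the preset correlation 11 of 36 lists shifted, and 0 did with an estimated one. The type I interferon list rose (mean 0.17, 12 of 14 positive, limma camera, adjusted p = 0.000189, and adjusted p = 0.219 with an estimated correlation), with Oasl2 at 0.59 (SE 0.19). The interferon-gamma list rose (mean 0.18, 11 of 12 positive, adjusted p = 0.000408, and adjusted p = 0.305 with an estimated correlation), with Gbp2 at 0.55 (SE 0.17). MHC class I genes rose (mean 0.18, 8 of 11 positive, adjusted p = 0.0192, and adjusted p = 0.575 with an estimated correlation), with B2m at 0.80 (SE 0.22). Striatal neuron markers fell (mean -0.40, 0 of 15 positive, adjusted p = 2.16e-06, and adjusted p = 0.45 with an estimated correlation), with the opioid peptide gene Pdyn at -0.59 (SE 0.19), Ppp1r1b, which encodes DARPP-32, at -0.73 (SE 0.32, other probes -0.47 and -0.21) and Gpr6, above background in 0 of 5 infected females and at least 1.17-fold lower there. Hippocampal markers rose (mean 0.47, 7 of 9 positive, adjusted p = 0.000381, and adjusted p = 0.219 with an estimated correlation), with Spink8 at 1.63 (SE 0.58) and Prox1 at 0.46 (SE 0.17). Glucocorticoid-induced genes fell (mean -0.24, 3 of 13 positive, adjusted p = 0.000902, and adjusted p = 0.219 with an estimated correlation), with Tsc22d3 at -0.57 (SE 0.17). Immediate early, myelin and MHC class II lists rose too, at adjusted p = 0.0126, adjusted p = 0.0192 and adjusted p = 0.0448. With an estimated correlation they stood at adjusted p = 0.426, adjusted p = 0.575 and adjusted p = 0.575. Ribosomal and respiratory chain lists rose by means of 0.30 and 0.26 (adjusted p = 5.96e-12 and adjusted p = 1.99e-09), and stood at adjusted p = 0.573 and adjusted p = 0.575 with an estimated correlation. Without female control replicate 3 the ribosomal mean was 0.05 (adjusted p = 0.189), the respiratory mean 0.03 (adjusted p = 0.74), and MHC class I and class II stood at adjusted p = 0.208 and adjusted p = 0.236. The preset call held in 4 of 10 fits without 1 mouse for MHC class II, in 7 for MHC class I, in 7 for immediate early genes (adjusted p = 0.12 without female infected replicate 3) and in 5 for myelin genes (adjusted p = 0.39 without female control replicate 2).

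In males alone, the smallest p values belonged to the calcium channel gene Trpv5 at 0.46 (SE 0.11), Lsm14b at -0.59 (SE 0.15, other probes -0.17 and -0.04), the splicing regulator gene Rbfox2 at -0.65 (SE 0.17, other probe -0.07), Cd200, a neuronal ligand that restrains microglia, at -0.49 (SE 0.12, other probe 0.01), Kng2, above background in 0 of 4 control males and at least 1.11-fold higher in infected males, and S100a14 at 0.46 (SE 0.13). None passed (limma, 0 of 11862 genes, smallest adjusted p = 0.994), with 405 features at an unadjusted p under 0.05, while Gm8909 passed with the replicate block within each sex. By camera with the preset correlation 14 of 36 lists shifted, and 0 did with an estimated one. The interferon-gamma list rose (mean 0.28, 11 of 12 positive, limma camera, adjusted p = 0.000114, and adjusted p = 0.204 with an estimated correlation), with Gbp3 at 0.37 (SE 0.16, other probe -0.02) and Ifi47 at least 1.24-fold higher. MHC class I genes rose (mean 0.24, 10 of 11 positive, adjusted p = 0.000281, and adjusted p = 0.204 with an estimated correlation), with B2m at 0.49 (SE 0.23) and H2-M3 at 0.35 (SE 0.16). The type I interferon list rose (mean 0.16, 13 of 14 positive, adjusted p = 0.00148, and adjusted p = 0.204 with an estimated correlation), with Ifit3 at 0.29 (SE 0.12). B and plasma cell markers rose (mean 0.39, adjusted p = 0.0113, and adjusted p = 0.204 with an estimated correlation), with Mzb1 at least 1.65-fold higher. Without male infected replicate 4 the preset calls held, with means of 0.16 for interferon-gamma, 0.13 for MHC class I and 0.10 for type I interferon genes.

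Other cell-type lists also shifted in males with the preset correlation. Choroid plexus and ependymal markers fell (mean -0.52, 2 of 12 positive, limma camera, adjusted p = 0.000204, and adjusted p = 0.324 with an estimated correlation), with Ecrg4 at -0.96 (SE 0.40), and the scores of male control replicates 2 and 4 lay above that of the highest infected male, at 0.78. Mural and meningeal markers fell (mean -0.24, 3 of 16 positive, adjusted p = 0.000321, and adjusted p = 0.204 with an estimated correlation), with the growth factor gene Igf2 at -0.78 (SE 0.23). Astrocyte markers fell (mean -0.16, 6 of 18 positive, adjusted p = 0.0124, and adjusted p = 0.32 with an estimated correlation), with Fgfr3 at -0.77 (SE 0.32, other probe -0.27) and Gfap at -0.52 (SE 0.24). Microglia markers of the unstimulated brain and synaptic genes fell at adjusted p = 0.00545 and adjusted p = 0.0198, and stood at adjusted p = 0.32 and adjusted p = 0.204 with an estimated correlation. Endothelial, monocyte and neutrophil, striatal and MHC class II lists rose, at adjusted p = 0.00545, adjusted p = 0.00545, adjusted p = 0.00549 and adjusted p = 0.0316. Their values with an estimated correlation were adjusted p = 0.229, adjusted p = 0.204, adjusted p = 0.427 and adjusted p = 0.364. Without male infected replicate 4 the MHC class II mean was -0.08 (adjusted p = 0.67), and without male infected replicate 1 the striatal, endothelial and B and plasma cell lists stood at adjusted p = 0.174, adjusted p = 0.12 and adjusted p = 0.0647. Without male control replicate 1 the unstimulated microglia, astrocyte and synaptic lists stood at adjusted p = 0.462, adjusted p = 0.182 and adjusted p = 0.489, and without male control replicate 4 the choroid plexus mean was -0.18 (adjusted p = 0.268).

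The difference between the infection effects of the sexes was tested as an interaction, female minus male. No gene passed (limma, 0 of 11862 genes, smallest adjusted p = 0.999), with 511 features at an unadjusted p under 0.05. The smallest p values belonged to Smco3 at 0.53 (SE 0.13), Ninl at -0.56 (SE 0.14), Medag at -1.16 (SE 0.28), Zfp606 at -0.56 (SE 0.15, other probe 0.17), Htra3 at 0.71 (SE 0.19) and Neu2 at -0.99 (SE 0.26). The striatal list differed by -0.65 on average, with 1 of 15 members positive (limma camera, adjusted p = 5.5e-07, and adjusted p = 0.471 with an estimated correlation), with Pdyn at -0.83 (SE 0.27) and Scn4b at -1.22 (SE 0.50). By mouse, the striatal score was 0.13 ± 0.40 in control females, -0.27 ± 0.30 in infected females, -0.06 ± 0.48 in control males and 0.19 ± 0.35 in infected males (SD, n = 5 except control males with n = 4, exact permutation p of the interaction 0.0777). By the same preset test 8 further lists differed: choroid plexus (0.52), hippocampal (0.46), immediate early (0.34), ribosomal (0.26), astrocyte (0.23), respiratory chain (0.19), heat shock (0.18) and odorant receptor (-0.06) genes, while 0 lists did with an estimated correlation, where the smallest adjusted p was 0.471. Without female control replicate 3 the ribosomal value was 0.02 (adjusted p = 0.834) and the respiratory chain value turned to -0.04, and without male control replicate 4 the choroid plexus value was 0.18 (adjusted p = 0.276). Of the 19 fits without 1 mouse the call held in 18 for astrocyte, 17 each for choroid plexus and ribosomal, 13 for hippocampal, 12 for respiratory chain, 11 for heat shock and 8 for odorant receptor genes. The immune lists did not pass in this interaction, with exact permutation p values of 0.687 for the interferon-gamma and 0.957 for the type I interferon score.

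**Figure D4:**
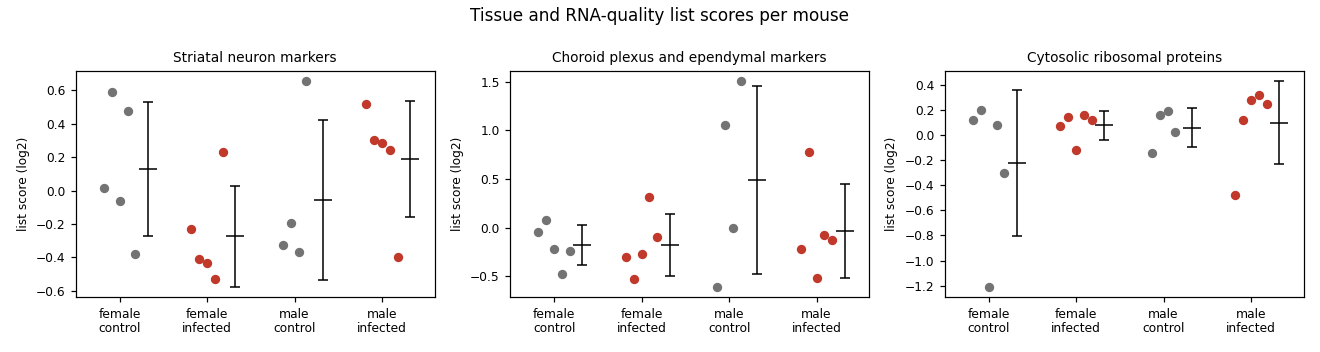
Score of the striatal, choroid plexus and cytosolic ribosomal lists in each mouse (points), grey for control and red for infected, with the group mean and SD as a bar. The striatal score averaged 0.13 in control and -0.27 in infected females, and -0.06 in control and 0.19 in infected males.

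Across the 11862 genes, which are not independent replicates, the female and male log2 fold changes had a Pearson correlation of 0.0244 and a Spearman correlation of -0.0163. Over 100 relabellings of infection within each sex the Pearson value ran from -0.671 to 0.66. It was -0.192 without female control replicate 3 and 0.185 without male infected replicate 1. No gene was called in both sexes, as none was called in either. At an unadjusted p under 0.05 in both sexes and in the same direction there were 18 features, where independent lists would share 8.17 and 19 of 100 relabellings of infection within each sex gave as many. Named after their values were seen, these included Slpi, Mzb1, B2m, H2-Q8, Ly6a and Prg2, an eosinophil granule protein gene, all higher, and Dbp and Tsc22d3, both lower.

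For themes linked to behaviour, 3 lists were drawn up from knowledge of this study and so are not independent evidence. Forebrain development regulators had a mean of 0.07 in females and -0.06 in males (limma camera, adjusted p = 0.376 and adjusted p = 0.222), with Fezf2 at 0.45 (SE 0.26) and -0.10 (SE 0.28). The female median of that list was -0.01, opposite in sign to its mean. Dopamine signalling genes had means of -0.11 and 0.08 (adjusted p = 0.563 and adjusted p = 0.329), with Drd2 at -0.37 (SE 0.25) and 0.39 (SE 0.26). Odorant and pheromone receptor genes had a mean of -0.01 in females (adjusted p = 0.987). They rose by a mean of 0.05 in males, with 95 of 137 positive (adjusted p = 0.00229, and adjusted p = 0.204 with an estimated correlation), by 0.02 in the average (adjusted p = 0.0214, and adjusted p = 0.387 with an estimated correlation), and their interaction was -0.06 (adjusted p = 0.049, and adjusted p = 0.549 with an estimated correlation). Without male control replicate 1 these stood at adjusted p = 0.072, adjusted p = 0.211 and adjusted p = 0.271. The other lists, among them complement (mean 0.05), T and NK cell (0.00), activated microglia (0.07) and reactive astrocyte markers (0.01), did not pass in any infection contrast (limma camera, averaged adjusted p = 0.389, 0.618, 0.0563 and 0.618).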

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

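The tests of RNA quality, of a single mouse, of both explanations of the striatal shift and of both explanations of the ribosomal shift, and the relabelling of the correlation between the sexes and the splits of the female pairs, were chosen only after the result was seen.

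The mice were split 100 times into groups of the same sizes, the real split included. As many lists as infection in females (11) came from 3 splits, highest other 12. As many as in males (14) came from 4, highest other 15, and as many as in the average (17) from 1, highest other 16. Each share lay under the criterion of 5 percent, without adjustment for the number of counts tried. The splits ignored the replicate numbers, and splits within numbered pairs were not run for males, where pairs correlated at 0.0867 to 0.467. Chance is therefore not excluded for the female and male counts. For the average, the splits argue against chance only where the replicate numbers are ignored. For the interaction 29 of 100 gave as many lists (9, highest other 16), and chance cannot be excluded. For the 4 infection counts of 0 genes, 100 of 100 splits gave as many, as any split must, so these shares are uninformative. The highest other stood at 1 in females, 4 in males, 0 in the average and 1 in the interaction. For the sex counts 1 of 100 splits, the real one, gave as many. These were 3 genes in controls with the highest other at 0, and 5 in infected mice with the highest other at 2. That is the smallest share 100 splits can give, and it argues against chance without excluding it. For the correlation of the female and male effects, 0.0244, 92 of 100 relabellings lay as far from 0, so chance cannot be excluded. In the 16 splits that part the 5 numbered female pairs the real one gave 0 genes and the highest other 1, which a count of 0 leaves uninformative. At an unadjusted p under 0.05 the real split gave 955 features, and with the pairs as a block 11 lists passed, where the highest other split gave 13. For each of these, 2 of 16 splits gave as many, the real one included, and 16 splits are too few for a share under 5 percent.

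The interferon lists were higher in infected mice, by 0.20 (SE 0.06) for the joint score of 26 genes. With the respiratory chain score as a covariate the difference was 0.19 (SE 0.06), and with the red blood cell score it was 0.18 (SE 0.06), which argues against RNA quality as these genes track it, and against blood left in the tissue, as the whole cause. Male infected replicate 4 stood highest for Igtp and Cd74, yet without it the difference was 0.15 (SE 0.04) with an exact permutation p of 0.00045, against 0.00057 with it, so that mouse does not carry the shift alone. No other mouse was left out in this test. Without male infected replicate 1 both interferon lists lost their call with an estimated correlation, as given in the results. Other results were weaker. Without the 4 arrays of lowest weight the interferon calls with an estimated correlation ended and the joint permutation called no list, as given in the results. Fry in the average gave adjusted p = 0.0739 for the interferon-gamma and adjusted p = 0.0525 for the type I interferon list. A response to the infection may account for the shift, as a hypothesis found and tested on the same mice, by permutations that ignored the replicate numbers. Parasite load was not measured in the sources used here and stays open.

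Neither the female nor the male striatal score differed clearly with infection (exact permutation p = 0.119 and exact permutation p = 0.373). On average the striatal markers moved opposite ways with infection in the 2 sexes. Within groups their members rose and fell together, with a mean correlation of 0.59 against 0.08 at the 95th percentile of 1000 random lists, as choroid plexus markers did (0.68), while hippocampal markers did so less (0.17). This is consistent with different amounts of striatum in the dissected tissue, though members under 1 regulator would also move together. Infection acting differently in the sexes stays open, at an exact permutation p of 0.078 for the interaction of the score.

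Ribosomal and respiratory chain genes were higher in infected mice, by 0.17 (SE 0.16) for the joint score of 127 genes, a difference within its error. Without the 4 arrays of lowest weight it was 0.12 (SE 0.06). These arrays include control and infected mice, so this test cannot tell whether arrays that stand apart account for the difference. The criterion for this test was made stricter, by taking in the error, after its value was seen: as first set, 0.12 left of 0.17 argued against these arrays as the cause. Leaving out female control replicate 3 alone lowered both list means further, as given in the results. Most of the averaged shift thus rests on that control array. Dim arrays are argued against, since both of the 2 arrays with the lowest score, female control replicate 3 (-1.16) and male infected replicate 1 (-0.53), were brighter than the median array. No biological explanation of this shift was tested.

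Of 216 groups of values examined for a mouse far from the rest of its group, 23 held one, where chance gives about 5 percent. The mean correlation with the other arrays was 0.970 for male infected replicate 1 and 0.966 for female control replicate 3. Male infected replicate 1 also stood apart by its scores for ribosomal (-0.48), respiratory chain (-0.56), synaptic (-0.27) and GABAergic (-0.18) genes and by Fezf2 at a log2 intensity of 6.36. Male infected replicate 4 stood apart by an MHC class II score of 1.83 and by Igtp at 7.75 and Cd74 at 9.41. Female control replicate 3 had a red blood cell score of -0.91 and B2m at 9.05. Male control replicate 1 had a red blood cell score of -0.02 and a synaptic score of 0.21, and male control replicate 4 a striatal score of 0.65 and Drd1 at 8.17. The thalamic, septal and hypothalamic score was 0.32 in male control replicate 3 and 1.22 in male infected replicate 2. Female infected replicate 2 had an olfactory bulb score of 0.01 and Uty at 5.12, female infected replicate 3 an unstimulated microglia score of 0.14 and Eif2s3y at 5.11, and female infected replicate 5 a dopamine signalling score of 0.13.

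By camera with the preset correlation the infection effect differed between the sexes, female minus male, for 9 lists, with means of -0.65 for striatal, 0.52 for choroid plexus and ependymal, 0.46 for hippocampal, 0.34 for immediate early, 0.26 for ribosomal, 0.23 for astrocyte, 0.19 for respiratory chain, 0.18 for heat shock and -0.06 for odorant and pheromone receptor genes. None of them passed with an estimated correlation, where the smallest adjusted p was 0.471.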

How the results depend on the processing

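The fits without the 4 arrays of lowest weight, with the respiratory chain or striatal score as a covariate and with a replicate block within each sex, and the scores over both sexes together, were chosen only after the data were seen. No infection contrast called a gene under any alternative with limma except the block within each sex, which called 1 gene, Gm8909, in males and 1, the same gene, in the average. That block left 11 lists in females, 14 in males, 16 in the average and 7 in the interaction. The plain replicate block, which ties the same number across all 4 groups, males included, gave 0 genes in each infection contrast, 3 and 5 genes for sex, and 11, 14, 17 and 9 lists, so it moved none of these counts, while the averaged calls with an estimated correlation ended as given in the results. For sex in controls, requiring detection on all 19 arrays left 1 gene, since Y-linked probes dark in females drop out, and array weights gave 5, with Xist and Cd6 added. For sex in infected mice that filter left 3 and the striatal covariate 3. The authors' processed values also gave 5 there, with Olig2 and Prl in place of Kdm6a and Uty, and a fit of only the groups compared gave 4, with CART called and Kdm6a and Uty lost. Without 1 mouse the count ran from 3 to 5, with 3 without male infected replicate 3, female infected replicate 1 or female infected replicate 4.

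For the lists, an estimated correlation left 0 in females, 0 in males, 3 in the average and 0 in the interaction, and fry 0, 1, 1 and 0. Without the 4 arrays the interaction had 5 lists. Without 1 mouse the interaction ran from 5 (male control replicate 4 or female infected replicate 4) to 11 lists and females from 7 (female infected replicate 1) to 11. For the scores, 0 lists passed within a sex, where a single list could not, and both sexes together gave 3, 3 with no background correction 1 with the authors' processed values and 0 without the 4 arrays of lowest weight. Of 8813 values of named genes under alternatives, 8775 kept their side of the threshold and either their sign or a value within 1 SE, 17 lost and 8 gained a call, 13 without a call changed sign by more than 1 SE, and 0 with a call changed sign. The cause was not tested for these changes, apart from the filter. The 8775 kept values say little about stability, as most of the named genes had no call in the main fit. The correlation of the female and male effects ran from -0.192 to 0.185 without 1 mouse. The slide block was not run because slides are not given. Dim probes limit the fold changes, which the offset pulls towards 0.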

Other observations

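Pituitary hormone transcripts, whose list was too short for a set test, varied between females. Prl, the prolactin gene, had a mean log2 intensity of 7.85 ± 1.24 in control females and 8.10 ± 2.77 in infected females (SD, n = 5 each), against 4.83 ± 0.67 in control males (SD, n = 4) and 4.60 ± 0.09 in infected males (SD, n = 5). Female infected replicate 1 stood at 11.80 for Prl and at 8.94 for Gh, the growth hormone gene. Prl was above background in 0 of 5 infected males, 1 of 4 control males, 4 of 5 infected females and 5 of 5 control females. Its sex difference in infected mice did not pass (limma, adjusted p = 0.51), while it passed with the authors' processed values. Prl and Gh were named after their values were seen.

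At an unadjusted p under 0.05 in both sexes and in the same direction there were 18 features, and 19 of 100 relabellings of infection within each sex gave as many, with a median of 8 and a highest other of 80. That count was made after the values were seen.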
